A study of Mus musculus with 2 samples.

How the data were processed

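Tissue of the cribriform plate region, which took in olfactory bulb and some nasal mucosa, was dissociated mechanically, and its cells were stained and sorted, per the labels' protocols. Cells of 5 healthy mice were pooled as 1 sample and cells of 5 mice with EAE as the other, per the labels. The deposited matrix holds raw UMI counts per gene and cell barcode as whole numbers, 31053 genes by 6272 barcodes and 47541728 UMIs in all. It was written by Cell Ranger with software version 3.1.0 and format version 2, per the file headers. The submitters' processing notes also name bcl2fastq and UMI-tools without versions. The aligner settings, genome build and annotation release are not given in the sources used here, so no coordinates are printed, and gene names and identifiers are those paired in the feature list. Whether read depth was equalised when the 2 libraries were joined is not given either. Barcodes end in 1 or 2, and no label, header or table used here ties a suffix to healthy or EAE mice. Suffixes were therefore kept as library 1 and library 2, and no condition was inferred from their values.

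All later values were computed here from the deposited counts with Python 3.11.15, Scanpy 1.11.5, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and igraph 0.11.9. Cells with at least 200 genes and at most 20% mitochondrial UMIs were kept, which left out 432 barcodes of library 1 and 512 of library 2. Scrublet, run per library as implemented in Scanpy, called 5 of the 5328 cells left (0.0938%), and these were removed. A call rate this low was treated as a failure of the caller, which was not tested, so doublets may remain among the kept cells. Counts were scaled per cell and log-transformed, and 2000 variable genes were chosen after the 273 genes of the response lists had been set aside, so that their levels would not shape the clusters. Cells were clustered on 30 principal components and 15 nearest neighbours with the Leiden method at resolution 1. Within a cell, a difference in captured RNA changes both depth and detection, so shares of cells with a UMI were computed after thinning each cell to 1000 UMIs and also on all UMIs.

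The marker genes of 23 cell types, the 15 response lists, the designs and the alternatives were fixed before the data were examined. The rule for naming clusters was written after a first look at another clustering of these cells. A cluster took the list with at least 3 markers among its 50 highest folds, was called mixed where 2 lists did, and was otherwise microglia-like when at least 5 of 7 microglia markers reached 100 CPM and 20 UMIs. Lists that shared most of their hits counted once, and a cluster with a median depth under 0.333 of that of its library and none of its markers among its 10 highest folds was to stay unnamed. Cluster 12, at 0.416, lay above that limit. The first version of the rule called cluster 7 microglia-like. A condition added afterwards, that no other list may have more markers than the cluster's own among its 10 highest folds, left cluster 7 unnamed. Names describe transcripts and were not checked against protein or an annotation by the authors.

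The designed comparison of EAE with healthy mice was not made because the libraries could not be mapped, and the designed fallback, lymphatic against blood endothelial cells, was not made because no lymphatic-endothelial-like cluster arose. In their place the response lists were described in microglia-like cells of each library and between classes of library 2. That class, the ratios of library 2 over library 1 and their percentiles were chosen after the data had been seen. Ratios over all genes were also computed. Apart from their median and the members of the response lists they are not reported, because the design set them aside for libraries that cannot be mapped. Named genes followed the fixed rule: per response list, the 4 members with the highest summed CPM and the 4 with the largest absolute log2 ratio among members with at least 20 UMIs, drawn on for examples, and always Pdpn, Pecam1, Ptprc, Cd274, Ccl21a, Icam1, Vcam1 and H2-Ab1. Members named as exceptions to a list's direction, and the P2ry12, Tmem119, Cx3cr1, Flt4, Lyve1, Mmrn1, Prox1 and Cldn5 values, fall outside that rule and were chosen after their values were seen. Values of some single genes are not reported here. Of the response genes, Mx2 and Cxcl11 were not used here because the feature list has no such symbol.

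UMIs were summed per class and library and divided by the class total to give CPM, with exact Poisson 95% intervals. For named genes with at least 100 UMIs in both libraries, the upper end of the interval lay within 21.1% of the value. Shares of cells have exact binomial 95% intervals, and a count of 0 is given with the share or CPM that 3 counts would make. Log2 ratios used a pseudocount of 10 CPM and folds none, so log2 ratios understate the change of genes at low levels. The interval of a list median is the exact order-statistic interval over its members and describes their spread. Random lists were matched in 20 bins of mean expression. Cells are not replicates, and no p-value was computed. Cells with lymphatic markers were counted by 13 of the 14 fixed markers, leaving out Cd9, which microglia also express. That set was chosen after the data had been seen. Barcodes of other types were counted by at least 3 markers that no other list holds and at most 2 microglia markers, also chosen afterwards. For the blood endothelial list, all 18 fixed markers were searched in this way.

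The steps were tested on simulated counts for 12286 genes drawn from the means and library sizes of the microglia-like cells, with 200 genes changed. For the 100 genes changed 2-fold the median recovered log2 ratio was 0.71, against a true value of 0.71 once the pseudocount is applied. For the 100 genes changed 4-fold it was 1.65 against 1.64. Unchanged genes had a median of -0.03, and 95.3% of the simulated means lay inside their 95% intervals. The counts were drawn with Poisson error alone, so this coverage was fixed by construction. It does not test the intervals against variation between cells, which the simulation left out.

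Alternatives were a stricter and no cell filter, doublets kept, Leiden resolutions of 0.5 and 2, variable genes with the response lists, TMM scaling (edgeR 4.0.16 under R 4.3.3, used for scaling factors only), totals without mitochondrial, ribosomal protein and haemoglobin genes, the mean of each cell's own CPM, a pseudocount of 1 CPM, all detected members and thinned cells. Leaving out the top 5% of doublet scores, adding cluster 7 to the microglia-like class and leaving cluster 11 out of it were chosen after seeing the data. TMM scaling shifted the log2 scale of library 2 over library 1 by 0.02 and that between classes by 0.82. Figures were drawn with matplotlib 3.10.9.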

Results

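Single-cell RNA sequencing was carried out on cells sorted from the region of the cribriform plate, the perforated bone through which olfactory nerves and lymphatic vessels leave the skull. The sort aimed at lymphatic endothelial cells, gated as positive for podoplanin and CD31, negative for the leukocyte protein CD45 and free of the dead-cell dye. Cells came from 10-week-old female C57BL/6J mice that were healthy or had experimental autoimmune encephalomyelitis (EAE), an induced inflammation of the central nervous system used as a model of multiple sclerosis. Each of the 2 groups was a pool of 5 mice and is 1 sample. The question set by the design was how neuroinflammation alters the lymphatic vessels of this site. The count matrix joins the libraries under barcode suffixes 1 and 2, and nothing in the labels or files used here says which suffix is which group. The values of library 1 and library 2 are therefore given side by side, and no comparison of EAE with healthy mice was made. With 1 library on each side there was no replicate and no test, so a difference between them compares these libraries and not the conditions. Intervals of shares, CPM and counts are exact 95% intervals and cover counting error only, whereas those of list medians describe the spread over list members.

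Library 1 held 3838 barcodes and 26269168 unique molecular identifiers (UMIs, each standing for 1 captured transcript). Library 2 held 2434 barcodes and 21272560 UMIs. After filtering, 3405 cells remained in library 1, with a median of 7333 UMIs and 2534 genes, and 1918 cells in library 2, with a median of 9782.5 UMIs and 2992 genes. Median mitochondrial shares of kept cells were 1.54% and 3.74%.

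Almost all kept cells carried the transcripts of microglia, the resident macrophages of the brain, and almost none carried those of lymphatic endothelium. Microglia-like cells made up 84.0% of library 1 (2861 of 3405 cells; interval 82.7% to 85.2%) and 93.8% of library 2 (1799 of 1918; 92.6% to 94.8%). The purinergic receptor gene P2ry12 had a UMI in 95.1% and 85.5% of all kept cells, at 1447 and 391 CPM, the summed UMIs of a gene scaled to the total of the cells. Tmem119, a surface marker of microglia, stood at 1216 and 807 CPM, and the fractalkine receptor gene Cx3cr1 at 2135 and 1307 CPM. At least 5 of the 7 microglia markers were detected in 94.5% of the cells of library 1 and 90.0% of those of library 2.

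The microglia-like class was held by different clusters in the 2 libraries. Clusters 1, 2, 5, 6 and 8 held nearly all of it in library 1, and clusters 3, 4, 9, 11 and 12 in library 2. In the first set, the 10 highest folds held the heat shock genes Hspa1a and Hspa1b beside P2ry12, Gpr34 and Fcrls in cluster 1, Gadd45b and Il1a in cluster 2, Cst3, Atf3 and Fos in cluster 5, P2ry12, Gpr34 and Fcrls in cluster 6, and Atf3 and Nr4a1 in cluster 8. In the second set they held H2-Ab1 and H2-Aa in clusters 3 and 4, Cxcl9 and Cd274 in cluster 9, Mki67 and Top2a of dividing cells in cluster 11, and Saa3 and Ccl5 in cluster 12. Within this class, clusters held mostly by 1 library are not read as separate cell types.

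Other classes were small. Cluster 7 held 322 cells, all of library 1 (9.46%), and stayed unnamed because the actin-bundling gene Fscn1, a dendritic cell marker, and no microglia marker stood among its 10 highest folds. Its 7 microglia markers summed to 17113 CPM, against 17059 CPM in the microglia-like cells of that library, and with cluster 7 added the microglia-like share of library 1 was 93.5%. Macrophage-like cells, led by Pf4, Ms4a7 and the mannose receptor gene Mrc1, made up 1.59% of library 1 (54 cells), and their cluster held no cell of library 2. Kept cells with at least 3 monocyte or macrophage markers that no other list holds and at most 2 microglia markers were also counted. There were 42 in library 1 and 26 in library 2. The full list summed to 28127 and 36229 CPM in microglia-like cells and to 31864 CPM in the macrophage-like cells of library 1. These counts therefore do not tell macrophages from microglia. Olfactory ensheathing-like cells, the glia of the olfactory nerve, led by Apod, Npy and Fabp7, made up 1.20% (41 cells) and 3.44% (66 cells). Their cluster also held microglia markers, at 12259 and 7599 CPM, and its name was lost under 4 of the alternative settings. Sensory-neuron-like cells, with the olfactory marker gene Omp and the odorant-signalling G protein gene Gnal, made up 0.206% (7 cells) and 1.93% (37 cells). Clusters 13 and 14 mixed markers of epithelial, bone, red blood and vessel cells and held 3.52% and 0.834%. Which cells passed the sort gate and the filter sets all of these shares.

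**Figure D1:**
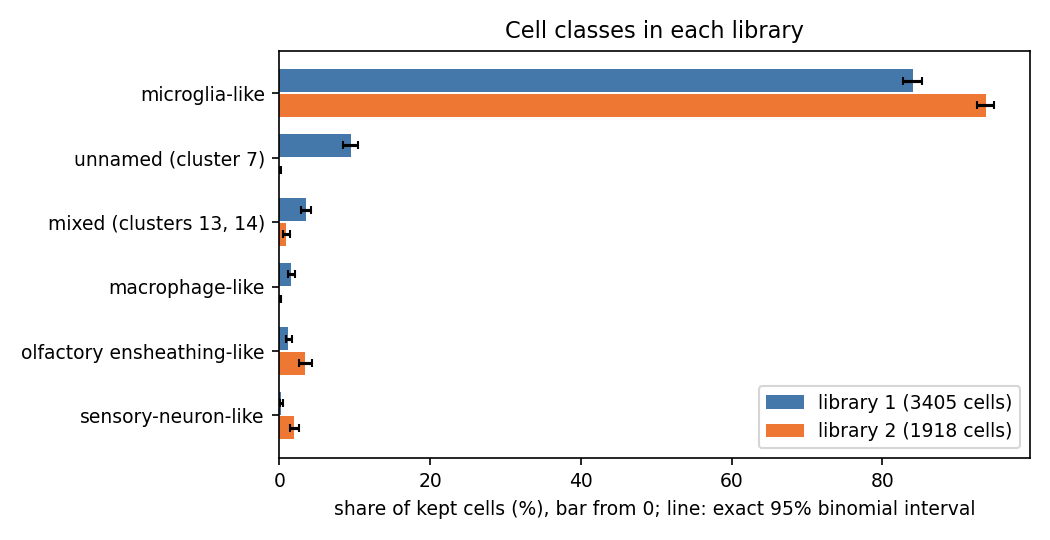
Share of kept cells in each class, in percent (horizontal axis, starting at 0), for library 1 (3405 cells) and library 2 (1918 cells); bars give the share and lines the exact 95% binomial interval. Microglia-like cells make up 84.0% and 93.8%, no other class named for a cell type exceeds 3.44%, and in library 1 the mixed clusters make up 3.52% and the unnamed cluster 9.46%.

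The genes of the sorted proteins went against the gate at the RNA level. Pdpn (ENSMUSG00000028583), which encodes podoplanin, had a UMI in 12 kept cells of library 1 (0.352%; 0.182% to 0.615%) and 4 of library 2 (0.209%; 0.0569% to 0.533%). Pecam1 (ENSMUSG00000020717), the gene of CD31, was detected in 12.2% of kept cells of library 1 and 5.32% of those of library 2. Both genes were detected together in 6 cells of library 1 and in 0 of 1918 cells of library 2, which allows a share of up to 0.156%. Ptprc (ENSMUSG00000026395), which encodes CD45, had a UMI in 81.9% and 81.0% of kept cells.

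Most lymphatic markers were close to absent. Prox1, a transcription factor gene of lymphatic endothelium, was the exception among those named here, with 380 UMIs in 8.52% of the kept cells of library 1 and 127 UMIs in 6.05% of those of library 2. Prox1 also had a UMI in 1 of the 37 sensory-neuron-like cells of library 2 (2.70%; 0.0684% to 14.2%), so its share in library 2 is not told apart from background. Ccl21a (ENSMUSG00000094686), a chemokine of lymphatic endothelium that guides dendritic cells, reached 262 UMIs in library 1 and 1 UMI in library 2. Of the Ccl21a UMIs of library 1, 193 lay in 1 cell and 61 in another. The lymphatic receptor gene Flt4 had 12 and 5 UMIs, the hyaluronan receptor gene Lyve1 25 and 1, and Mmrn1 11 and 0, where 0 allows up to 0.148 CPM. At least 3 of 13 lymphatic markers were found in 8 kept cells of library 1 and 3 of library 2, of which 2 and 1 had at most 2 microglia markers. At least 4 were found in 3 cells of library 1 and in 0 of the 1918 cells of library 2, which allows up to 0.156%. Of the 3 cells of library 1 with at least 4, 1 had at most 2 microglia markers. It held 5485 UMIs, with 193 of Ccl21a, 10 of Prox1, 5 of Flt4, 5 of Mmrn1 and 29 of the endothelial claudin gene Cldn5, and no UMI of Ptprc. The second held 33027 UMIs, 8 lymphatic and 6 microglia markers, and the third held 8244 UMIs and all 7 microglia markers. No cluster was lymphatic-endothelial-like under the main or any alternative setting, so the comparison of lymphatic with blood endothelial cells fixed in the design was not made. Without a cell filter, a blood-endothelial-like cluster held 154 barcodes of library 1 and 23 of library 2.

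**Figure D2:**
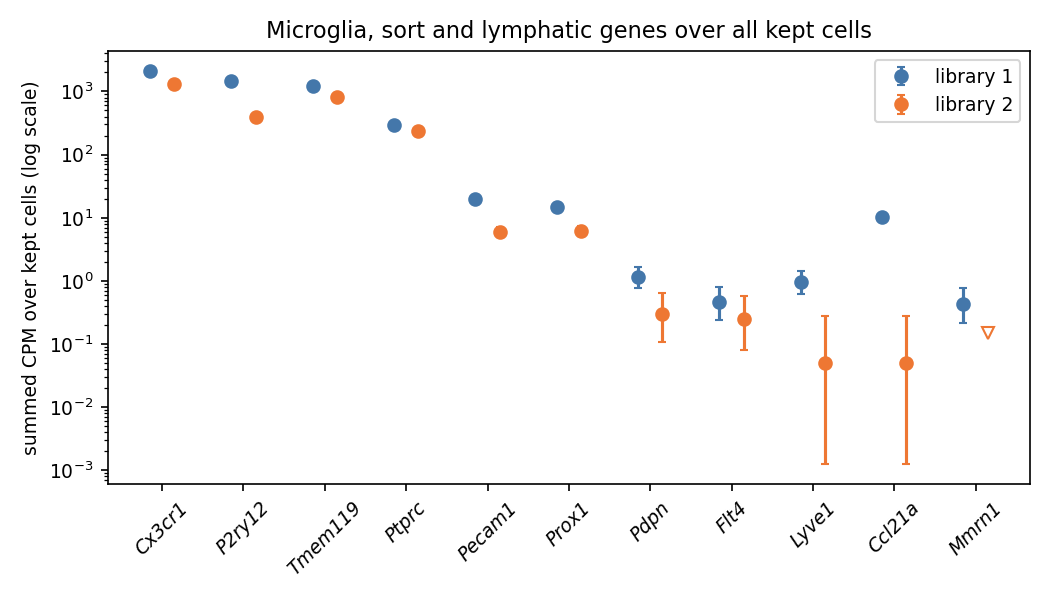
Summed CPM over all kept cells (log axis) of microglia, sort and lymphatic genes in library 1 and library 2, with exact 95% Poisson intervals; the open triangle marks the upper limit of 0.148 CPM that a count of 0 allows for Mmrn1 in library 2. P2ry12 stands at 1447 and 391 CPM, and Pdpn at 1.16 and 0.297 CPM.

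In the microglia-like cells, genes of antigen presentation and interferon response were higher in library 2, and stress and immediate early genes were higher in library 1. Values are summed CPM over 2861 and 1799 cells (21589868 and 19007460 UMIs), and log2 ratios of library 2 over library 1 carry a pseudocount of 10 CPM. Cell type markers also differed between the libraries within the class. The 7 microglia markers summed to 17059 CPM in library 1 and 10517 CPM in library 2, with P2ry12 at 1490 and 406 CPM and Siglech at 788 and 306 CPM. Monocyte or macrophage markers summed to 28127 and 36229 CPM, a list that the macrophage-like cells of library 1 held at 31864 CPM. Its level therefore does not tell macrophages from microglia. Astrocyte markers summed to 106 and 270 CPM and platelet or megakaryocyte markers to 61.6 and 10.4 CPM. Osteoblast or chondrocyte markers (78 and 171 UMIs) and T or NK cell markers (412 and 176 UMIs) also differed more than 2-fold in CPM, the first higher in library 2 and the second in library 1. The median log2 ratio over all 12306 genes with at least 20 UMIs was -0.01. Each list median is given with an exact interval over its members and its percentile among 10000 random lists matched on expression, which describes these libraries only.

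All 18 genes of MHC class I and antigen processing were higher in library 2, with a median log2 ratio of 1.66 (1.30 to 2.23; percentile 100). The class I heavy chain genes H2-K1 and H2-D1 stood at 1107 and 1767 CPM in library 1 and at 5223 and 6364 CPM in library 2. B2m, the light chain of class I molecules, stood at 1800 and 5380 CPM, and the peptide transporter gene Tap1 at 57.9 and 468 CPM. Nlrc5, a transactivator of class I genes, was 21.0-fold higher in library 2 (2.92 and 61.3 CPM). H2-T23 stood at 282 and 1258 CPM. H2-Q6 (71.4 and 394 CPM) and H2-Q7 (91.4 and 1098 CPM) are near-identical copies whose reads the counting could split, so their single values are uncertain.

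Of 14 genes of MHC class II and costimulation, 12 were higher in library 2, with a median log2 ratio of 1.49 (0.21 to 4.92; percentile 100). The class II chain genes H2-Ab1 (ENSMUSG00000073421), H2-Aa and H2-Eb1 stood at 63.4, 43.5 and 36.8 CPM in library 1 and at 2208, 2037 and 1706 CPM in library 2. Cd74, the invariant chain that escorts class II molecules, stood at 643 and 9298 CPM, and the lysosomal protease gene Ctss at 4890 and 9877 CPM. The 2 exceptions were H2-Ob (17.8 and 14.7 CPM) and the costimulatory gene Cd80 (10.3 and 8.10 CPM).

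All 21 genes of the type I interferon response were higher in library 2, with a median log2 ratio of 2.16 (1.75 to 2.73; percentile 100). Irf7, the transcription factor that amplifies type I interferon, stood at 10.2 and 183 CPM, and the ubiquitin-like modifier gene Isg15 at 37.7 and 306 CPM. Ifi27l2a was 13.6-fold, Oasl2 22.8-fold, Rtp4 12.2-fold and Trim30a 3.78-fold higher in library 2. All 21 genes of the interferon gamma response were also higher there, with a median of 2.28 (1.16 to 3.03; percentile 100). The guanylate-binding protein genes Gbp2 and Gbp4 stood at 15.9 and 1.76 CPM in library 1 and at 507 and 111 CPM in library 2, and the immunity-related GTPase gene Iigp1 at 4.40 and 238 CPM. Reads of Gbp genes can be shared among close copies, so single Gbp values are uncertain. The transcription factor genes Irf1 and Irf8 differed less, by 1.36-fold and 1.29-fold. With a pseudocount of 1 CPM the medians of both interferon lists were larger, at 2.99 and 3.15.

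Genes of the dissociation and immediate early list went the other way. All 21 were lower in library 2, with a median log2 ratio of -1.31 (-1.86 to -0.98; percentile 0). Jun and Fos, subunits of the AP-1 transcription factor, stood at 10544 and 9232 CPM in library 1 and at 3046 and 3724 CPM in library 2. Junb stood at 5928 and 2357 CPM, and the stress-induced factor gene Atf3 at 7966 and 1080 CPM. The small heat shock gene Hspb1 was 26.6-fold higher in library 1. Hspa1a and Hspa1b, near-identical Hsp70 genes whose reads the counting could split, were 8.86-fold and 9.42-fold higher there. The median share of a cell's UMIs from this list was 6.21% in library 1 and 2.36% in library 2, so the libraries differed in this list as well as in the MHC and interferon lists.

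**Figure D3:**
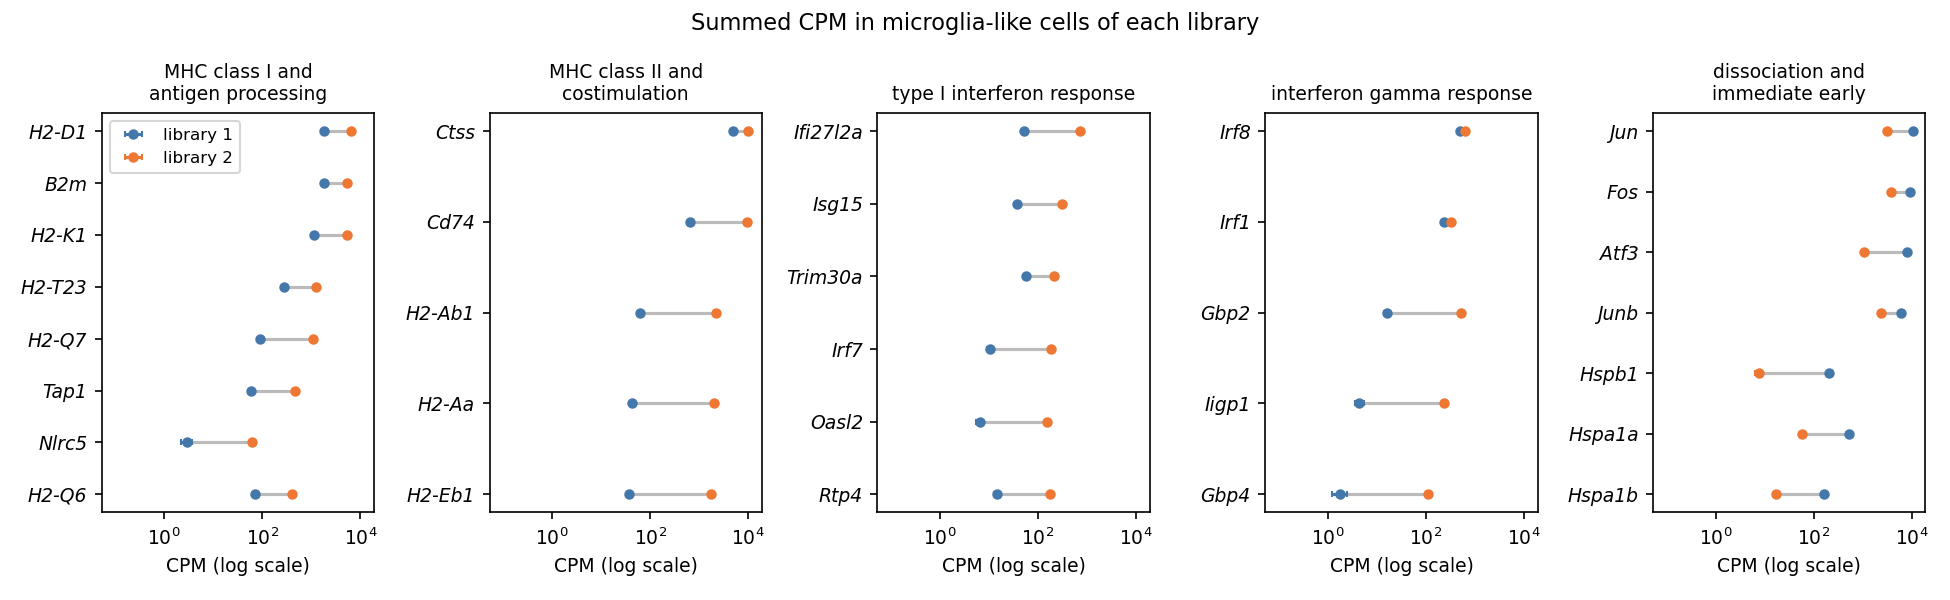
Summed CPM (log axis) in microglia-like cells of library 1 and library 2 for named genes of 5 gene lists, with exact 95% Poisson intervals and grey lines joining the 2 values of a gene. All genes shown in the first 4 panels lie higher in library 2, such as H2-Ab1 at 63.4 and 2208 CPM, and all in the last lie higher in library 1, such as Atf3 at 7966 and 1080 CPM.

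Checkpoint and regulatory genes were split. Of 13 genes, 9 were higher in library 2, with a median log2 ratio of 0.33 (-0.57 to 0.70; percentile 99.4), but the summed level of the list was lower there (1799 and 1531 CPM). Cd274 (ENSMUSG00000016496), which encodes the inhibitory ligand PD-L1, was 12.6-fold higher in library 2 (8.94 and 113 CPM), and the galectin gene Lgals3 5.19-fold higher. The 4 genes that were higher in library 1 were Vsir, which encodes the inhibitory receptor VISTA (774 and 354 CPM), Cd276 (10.7 and 0.894 CPM), the ectonucleotidase gene Entpd1 (288 and 232 CPM) and Tgfb1 (337 and 224 CPM). Cd47, the gene of a signal against phagocytosis, stood at 209 and 296 CPM.

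Chemokine genes went both ways. Of 14 genes of the chemokine, cytokine and S1P list, 8 were higher in library 2, with a median of 0.39 (-0.07 to 2.78; percentile 99.7) and summed levels of 1750 and 5849 CPM. The median turned to -0.01 when all members detected were counted. The monocyte attractants Ccl2 and Ccl7 stood at 613 and 79.5 CPM in library 1 and at 2738 and 604 CPM in library 2. Ccl5, which attracts T cells, stood at 27.5 and 870 CPM. The interferon-induced ligands of CXCR3, a chemokine receptor of T cells, Cxcl9 and Cxcl10, stood at 17.8 and 396 CPM in library 1 and at 337 and 754 CPM in library 2. Cxcl2, an attractant of neutrophils, was 21.5-fold higher in library 1 (265 and 12.4 CPM).

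Of 12 leukocyte adhesion genes, 4 were higher in library 2 and 8 were lower, with a median of -0.15 (-0.55 to 0.03; percentile 9.74). Vcam1 (ENSMUSG00000027962), the ligand of the integrin VLA-4, was 5.62-fold higher in library 2 (33.8 and 190 CPM), and the hyaluronan receptor gene Cd44 8.61-fold higher. The other 2 were Madcam1 and Cd99l2, at under 10 CPM in both libraries. The junctional adhesion genes Jam2, Jam3 and F11r were higher in library 1, with Jam2 at 59.0 and 9.89 CPM. Icam1 (ENSMUSG00000037405), which was not part of this list, stood at 377 and 267 CPM. Of 14 genes of the NF-kappaB and TNF response, 5 were higher in library 2, with a median of -0.19 (-1.42 to 0.15; percentile 14.2). The feedback inhibitor genes Nfkbia and Tnfaip3 stood at 2667 and 577 CPM in library 1 and at 992 and 189 CPM in library 2. Nfkbiz was 3.08-fold higher in library 1, and Cebpb stood at 662 and 713 CPM.

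Proliferation genes were higher in library 2 for 15 of 18 members, with a median of 0.51 (0.34 to 0.90; percentile 100) that became 1.11 with a pseudocount of 1 CPM. The list summed to 690 and 770 CPM. Cluster 11, led by genes of dividing cells, held 0.699% of the microglia-like cells of library 1 (20 cells) and 4.61% of those of library 2 (83 cells), and without it the median was 0.21. The division genes Ube2c, Birc5 and Ccnb2 were 3.96-fold, 3.77-fold and 4.78-fold higher there, at levels of at most 34.1 CPM, and Mki67 stood at 9.40 and 28.3 CPM. The 3 exceptions were the replication clamp gene Pcna (92.8 and 54.2 CPM), Mcm3 (38.7 and 33.7 CPM) and Hmgb2 (405 and 343 CPM).

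The remaining lists differed little at their medians. Glycolysis and hypoxia genes had a median of 0.15 (-0.07 to 0.51; percentile 95.2; 11 of 17 higher in library 2), with the glycolytic enzyme genes Gapdh at 640 and 919 CPM and Pkm at 231 and 358 CPM. Cell death genes had a median of -0.06 (-0.54 to 0.30; percentile 37.3; 7 of 14 higher), with the p53 targets Cdkn1a at 303 and 114 CPM and Bbc3 at 205 and 67.4 CPM. That median was 0.03 when mitochondrial, ribosomal protein and haemoglobin genes were left out of the totals. Endothelial junction genes had a median of -0.26 (-0.55 to -0.01; percentile 0.53; 1 of 10 higher, Ocln at 1.99 and 8.68 CPM), which was -0.61 with a pseudocount of 1 CPM. Lymphatic growth and identity genes had a median of -0.24 (-0.95 to 0.13; percentile 2.06; 2 of 8 higher, Nfatc1 and Angpt2). Among them the homeobox gene Hhex stood at 96.6 and 66.0 CPM and the transcription factor gene Nfatc1 at 39.7 and 40.4 CPM. Matrix and basement membrane genes had a median of -0.04 (-1.08 to 1.62; percentile 25.3) but a mean of 0.18, and the 3 of 7 that were higher in library 2 were Mmp14 (13.7 and 62.8 CPM), Mmp2 (13.9 and 27.8 CPM) and Fn1 (4.47-fold). In the same list the basement membrane gene Nid2 was 18.5-fold higher in library 1.

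Shares of cells with a UMI followed the summed levels once each cell was thinned to 1000 UMIs, which left out 12 microglia-like cells of library 1 and 3 of library 2. H2-Ab1 was then detected in 3.90% of microglia-like cells of library 1 (3.22% to 4.67%) and 69.4% of those of library 2 (67.2% to 71.6%), and in 13.4% and 91.3% with all UMIs. Cd274 was detected in 0.878% and 8.85% at 1000 UMIs, and in 5.38% and 51.4% with all UMIs. For Vcam1 the shares were 2.81% and 15.5%, with all UMIs 13.9% and 65.4%. For Icam1 they were 28.7% and 21.5%, with all UMIs 81.9% and 77.4%. Ptprc was detected in 26.1% and 19.6% at 1000 UMIs and in 84.7% and 84.4% with all UMIs, and Pecam1 in 1.58% and 0.501%, with all UMIs 11.6% and 5.39%. Pdpn and Ccl21a had no UMI in 2849 and 1796 thinned cells, which allows up to 0.105% and 0.167%. With all UMIs, Pdpn was detected in 2 and 0 of these cells and Ccl21a in 3 and 1. In the 37 sensory-neuron-like cells of library 2, taken as background, none of these genes had a UMI at 1000 UMIs, which allows up to 8.11%. With all UMIs, H2-Ab1 was detected in 4 of the 37 (10.8%), Cd274 in 2 (5.41%), Icam1 and Pecam1 in 1 each (2.70%), and Ptprc, Vcam1, Pdpn and Ccl21a in none. Median depths were 9783 UMIs in the microglia-like and 11227 UMIs in the sensory-neuron-like cells. At 1000 UMIs the Pdpn, Ccl21a and Pecam1 shares of library 2 lay below 8.11% and the interval of Cd274 (7.58% to 10.3%) included it, so these 4 are not told apart from background at that depth. Library 1 held only 7 sensory-neuron-like cells (median 13704 UMIs), too few to set a background, and none of these genes had a UMI in them.

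Between 2 classes of library 2, transcripts of most response lists were higher in the microglia-like than in the sensory-neuron-like cells. MHC class I genes summed to 23762 CPM in the first and 387 CPM in the second, with a median log2 ratio over 18 genes of 4.73 (3.34 to 5.94). MHC class II genes summed to 26853 and 86.8 CPM (median 4.86; 1.83 to 6.97), type I interferon genes to 2761 and 322 CPM (2.59; 2.06 to 3.70) and interferon gamma genes to 3780 and 48.7 CPM (3.47; 2.36 to 4.27). The dissociation list summed to 24792 and 3006 CPM (4.37; 2.25 to 5.46), the NF-kappaB list to 2666 and 430 CPM (2.56; 1.07 to 3.65) and the chemokine list to 5849 and 78.3 CPM (4.16; 1.16 to 5.98). Checkpoint genes had a median of 1.33 (0.21 to 4.27), adhesion genes 1.88 (0.08 to 3.33), cell death genes 0.87 (0.49 to 3.54) and proliferation genes 1.25 (0.82 to 1.85), although the proliferation sum was higher in the sensory-neuron-like cells (770 and 1344 CPM). Junction genes were lower in microglia-like cells (-0.94; -2.44 to -0.09), and glycolysis (-0.97; -1.83 to 0.58) and lymphatic growth genes (0.10; -1.16 to 2.93) had intervals on both sides of 0. Matrix genes, of which only 4 had enough UMIs, had a median of 1.02. TMM scaling shifted the scale of the ratio by 0.82, with which the junction median was -0.23, the glycolysis median -0.18 and the MHC class I median 5.27. The ensheathing-like cells of library 2 held these lists too, with MHC class I at 19247, MHC class II at 18957, type I interferon at 3216 and interferon gamma genes at 3615 CPM, beside microglia markers at 7599 CPM against 10517 CPM in the microglia-like cells. In those of library 1, MHC class I genes summed to 5101 CPM and microglia markers to 12259 CPM.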

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

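The test of the placental pattern below was chosen after the result was seen.

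Placental transcripts, which are foreign to the tissue taken, sat in a barcode sequence present in both libraries. A set of 40 placental genes, gathered after the data had been seen, had 244 UMIs in library 1, of which 239 lay in that barcode, and 173 UMIs in library 2, of which 169 lay in it. They made up 31.2% of the barcode's 765 UMIs in library 1 and 30.6% of its 552 UMIs in library 2, led by the trophoblast genes Tpbpa (121 and 79 UMIs), Tpbpb (36 and 27) and Prl8a9 (16 and 12). They drew attention as a signal that no comparison used.

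Of the placental UMIs of library 2, 97.7% lay in the barcode that also held 98.0% of those of library 1. Barcodes also present in library 1 made up 0.329% of those of library 2 (0.142% to 0.647%). The share that chance alone would give was not computed, so this share alone does not decide on a chance meeting of different cells in 1 barcode. The placental values argue against such a meeting for this barcode. It held nearly all placental UMIs of each library, at 31.2% and 30.6% of its own UMIs. Among the 8 shared pairs, 3 had under 1000 UMIs in both libraries. These 3, the placental barcode among them, were kept as cells of the mixed clusters in both libraries. Reads carried over from another library together with their barcode stay open as an untested explanation, and no biological explanation was tested.

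Among barcodes left out by the filter or as doublets, which no comparison used, 30 of library 1 and 179 of library 2 held at least 3 markers of olfactory ensheathing or Schwann cells and at most 2 microglia markers. By the same criterion, 31 left-out barcodes of library 1 and 11 of library 2 held markers of the blood endothelial list. The clearest lymphatic cell also held genes of that list, with 29 UMIs of Cldn5, 4 of Cdh5 and 1 of Pecam1. These counts therefore do not tell blood from lymphatic endothelium. Markers that several lists hold were not counted here.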

How the results depend on the processing

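The alternatives that left out the top 5% of doublet scores, that added cluster 7 to the microglia-like class and that left cluster 11 out of it were chosen after the data had been seen. No paired analysis was possible because the libraries could not be mapped to the groups and each group is 1 sample. No result with an interval on 1 side of 0 changed sign. The MHC class I median of library 2 over library 1 in microglia-like cells ranged from 1.65 to 1.80 over 15 alternatives, that of MHC class II from 1.42 to 1.64 and that of the dissociation list from -1.33 to -1.18. Of the values under alternatives, 60 class shares stayed within the counting interval and 20 moved beyond it. The 60 include the lymphatic-endothelial-like shares and the macrophage-like share of library 2, which held no cell under any setting and so could not show stability. For shares of cells with a UMI, 4 stayed and 16 moved. List medians were set against the wider interval over list members, which is no counting error; 218 stayed within it and 5 moved beyond it in microglia-like cells, and 188 and 6 between classes. Where values moved, the cause was not tested, except that shares of cells with a UMI rise with the UMIs kept by construction. Alternatives for gene levels in the lymphatic-endothelial-like class, which the design also set for all its genes, were not run because no such class was found. Ratios over all genes in microglia-like cells were not run under the alternatives either. Depth limits the genes named at a few CPM and all shares in the 7 and 37 sensory-neuron-like cells.

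The microglia-like share of library 1 was 87.0% with at least 500 genes and at most 10% mitochondrial UMIs, 81.0% with no cell filter, 79.1% with doublets kept, 93.2% at resolution 0.5, 81.5% with response genes among the variable genes, 91.1% without the top 5% of doublet scores and 93.5% with cluster 7 added. That of library 2 was 70.6% with no cell filter, 89.3% at resolution 0.5 and 89.5% with response genes among the variable genes. The ensheathing-like share was 0 in both libraries with the stricter filter, at resolutions 0.5 and 2 and with response genes among the variable genes, and 12.1% in library 2 with no cell filter. The macrophage-like share of library 1 was 0 at resolution 0.5.

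With a pseudocount of 1 CPM, the medians of library 2 over library 1 were 2.99 for type I interferon, 3.15 for interferon gamma, -0.61 for junction and 1.11 for proliferation genes, and without cluster 11 the proliferation median was 0.21. The medians of microglia-like over sensory-neuron-like cells were then 6.13 for MHC class I, 4.04 for type I interferon, 5.18 for interferon gamma, 3.45 for adhesion, 3.92 for NF-kappaB and 3.49 for proliferation genes. Chemokine genes turned to -0.01 with all members detected and cell death genes to 0.03 without mitochondrial, ribosomal protein and haemoglobin genes, both inside their intervals.

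In microglia-like cells of library 1, shares at 2000 UMIs and with all UMIs were 3.70% and 11.6% for Pecam1, 45.5% and 84.7% for Ptprc, 1.67% and 5.38% for Cd274 and 5.34% and 13.4% for H2-Ab1. In library 2 they were 1.40% and 5.39% for Pecam1, 37.1% and 84.4% for Ptprc, 16.5% and 51.4% for Cd274 and 80.6% and 91.3% for H2-Ab1.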

Other observations

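Of the tests below, only the matchings of cells on their dissociation genes and on their microglia markers were chosen before their results were seen, and the others were chosen after.

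Prox1, the transcription factor that sets lymphatic endothelial identity, was detected in 290 kept cells of library 1 (8.52%) and 116 of library 2 (6.05%), far more than any other lymphatic gene searched here apart from Cd9. Of these cells, 98.6% in library 1 and 93.1% in library 2 held at least 5 of the 7 microglia markers, against 94.5% and 90.0% of all kept cells. Another lymphatic marker was found in 4.14% of Prox1 cells of library 1 (2.16% to 7.12%) and 4.31% of those of library 2 (1.41% to 9.77%), against 1.28% and 1.33% of cells without Prox1. These shares used all UMIs, and the cells compared were not matched on depth, which changes detection. They therefore do not show that Prox1 goes with other markers, and the Prox1 share of library 2 was not told apart from background.

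Sensory neurons and astrocytes were found more often among left-out barcodes than among kept ones, counted as barcodes with at least 3 markers of that list alone and at most 2 microglia markers. Sensory neuron markers were held so by 43 left-out and 21 kept barcodes of library 1 and by 171 and 45 of library 2, and astrocyte markers by 45 and 14 and by 86 and 23. Olfactory bulb neuron markers went both ways, with 16 left-out and 7 kept barcodes in library 1 and 15 and 31 in library 2. Median mitochondrial shares of barcodes removed by the filter were 63.9% and 51.3%. In the macrophage-like cells of library 1, Lyve1, which tissue macrophages also express, stood at 47.0 CPM, from 23 of the 25 Lyve1 UMIs of that library, which lay in 7.41% of these 54 cells. H2-Ab1 stood there at 781 CPM, beside microglia markers at 8798 CPM.

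Nearly all kept cells carried microglia markers and few carried lymphatic ones, although the sort aimed at the reverse. Free microglia RNA is argued against, since sensory-neuron-like cells held the 7 microglia markers at 0.382% of their level in microglia-like cells of library 2 (37 cells) and 0.546% in library 1 (0.249% to 1.04%), there in only 7 cells. Ensheathing-like (12259 and 7599 CPM), mixed (5313 and 7271 CPM) and macrophage-like cells (8798 CPM in library 1) held far more, which free RNA shared by all droplets does not give, and doublets stay open for these classes. Loss of lymphatic cells to the filter stays open, since 0 of the 949 left-out barcodes held at least 3 lymphatic markers, but at their depth (median 457 UMIs outside mitochondrial genes) the clearest lymphatic cell kept 3 in only 61.1% of random draws. A sort gate that let microglia through, or a matrix that does not hold the labelled cells, stays open. Ptprc had a UMI in 81.6% of kept cells (80.5% to 82.6%). It also had one in 84.7% and 84.4% of the microglia-like cells, so that share restates the pattern and supports neither. The test does not separate these 2 explanations, and surface protein was not measured in the data used here.

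MHC and interferon genes were higher in the microglia-like cells of library 2. Another make-up of the class, with fewer microglia in library 2, is argued against as the whole cause, since the median log2 ratio over the 4 lists was 1.73 (1.49 to 1.98) between 927 cells of each library matched on their share of microglia marker UMIs, against 1.99 between all cells. A difference in dissociation response is argued against as the whole cause, since it was 2.01 (1.49 to 2.38) between 755 cells of each library matched on their dissociation share, after which the median of the dissociation list was 0.02. A batch difference cannot be told apart from a difference between samples, because the dissociation list also differed (-1.31) and no other library of either condition was analysed here. EAE against health, which the design names, stays open and untested, since neither library could be mapped.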
